A study of Homo sapiens with 6 samples.

How the data were processed

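Total RNA of PC3 cells, a human prostate cancer line derived from a bone metastasis, was measured on 6 Agilent gene expression arrays of 1 colour, 3 from cells carrying a scrambled short hairpin RNA (shControl) and 3 from cells carrying a hairpin against MEK5 (shMEK5). Groups and replicate numbers were taken from the sample labels. Per the file headers, the deposited scanner files hold spot intensity values of array design 026652, read with Agilent Feature Extraction 12.0.2, which the submitters' processing notes name as well. The processed intensity was background-subtracted and detrended within each array, per the file headers, with no scaling between arrays. The flags for spots well above background, for outliers and for saturation are the deposited ones, set by Feature Extraction per the file headers. A separate deposited table holds the authors' processed values on a log2 scale for 10056 probes, of which 10032 matched a probe of the scanner files. Those log2 values correlated with the log2 signal of the same array at Pearson r between 0.992 and 0.999 across probes, and their medians were 6.24, 5.83 and 6.86 for shControl replicates 1, 2 and 3 and 6.99, 6.39 and 6.48 for shMEK5 replicates 1, 2 and 3. Their normalization, any centring and the choice of probes stayed unknown, so the authors' log2 values served only as an alternative.

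The log2 of the processed intensity was averaged over the spots of each probe, without outlier spots and control spots, and the 75th percentile of each array was subtracted. Each array held 43118 spots for 34127 probes outside the controls. Probes well above background on at least 3 of the 6 arrays were kept, and the probe with the highest mean stood for its gene. Probes of OSCAR and of TBC1D1 passed in opposite directions. A gene symbol was assigned to 26377 probes through the accession, to 2223 through the current symbol and to 342 through an older symbol, with a RefSeq gene table, 1310 kept the name of the file, and 3875 had no symbol. Probe coordinates are those of the files, on build hg19. With no annotation of that build used here, exons were not assigned. Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over 14637 genes and a threshold of 0.05 on the adjusted p. Tables were prepared and plots drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

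A gene that no probe showed well above background on any array of a group has only a bound in that group. Its fold is given as "at least", from the mean of the brighter group over the mean, per dim array, of the higher of the gene's own value and the lowest value of any probe well above background. The fitted log2 difference of such a gene is no bound.

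The design, 36 gene lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. Named were MAP2K5 and MAPK7, the 12 largest rises and 12 largest falls among genes past the threshold with groups that do not overlap and with the higher group well above background throughout (symbols that only give a locus, clone, reading frame or family number were passed over), up to 3 rising and 3 falling members of each list past the threshold (where none passed, the member with the largest difference), and every measured member of the MEK5-ERK5 cascade. Some genes that this rule names are not reported here. A list with at least 5 measured members was tested with limma's camera at a preset correlation of 0.01 over the 14214 genes with a value on every array, again with an estimated correlation, and with fry. Those tests covered 35 lists.

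The headers put the arrays on 2 slides. Slide 1 held the 3 shControl arrays and shMEK5 replicate 1, and slide 2 held shMEK5 replicates 2 and 3. With slide as a block the estimated difference equals that within slide 1, because slide 2 holds a single group. The other alternatives were normexp background correction, median and quantile scaling, other filters on dim probes, outlier spots kept, other rules for genes with several probes, an intensity trend, slide as a random block, the replicate number as a block, the authors' values, and the omission of each array in turn. A second normexp correction, with its noise taken from the 153 negative control spots, was added after the data were seen, because the planned one set floors that differed between arrays. Where an alternative changed the signal values or the filter on dim probes, the probe with the highest mean was chosen again. A gene's value there can therefore come from another probe.

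The gene test was tested on simulated data before use. Each of 10 simulations of 3 against 3 arrays changed 200 of the 14637 genes. The gene test recovered 10.7% of genes changed 2-fold, 80.6% of those changed 4-fold and 95.0% of those changed 8-fold. Of its calls 4.93% were false. The simulated spread was drawn from the model that the test assumes, equal in both groups and with no slide effect. The false share therefore does not carry over to the data. In the data far more genes passed, 3284. The Benjamini-Hochberg adjustment depends on how many genes change, so the shares recovered hold only for the simulated setting. The list test on 14214 simulated genes called all 10 lists shifted by 1 on the log2 scale and 0 of 300 unshifted lists. The simulated genes varied independently, so this does not check the test on lists whose members vary together. In the data the estimated correlation reached 0.246, in the list of ERK1/2 feedback and output. The number of arrays limits the precision of each value.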

Results

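The transcripts of PC3 prostate cancer cells were compared between cells stably carrying a hairpin against MEK5 and cells carrying a scrambled hairpin, with 3 arrays in each group. MEK5, the product of MAP2K5, is the kinase that phosphorylates ERK5, the product of MAPK7. The median processed signal was 71.8, 112 and 68.5 on shControl arrays 1, 2 and 3, and 62.8, 30.9 and 33.2 on shMEK5 arrays 1, 2 and 3, and the last pair lay on a slide of their own. Between 53.1% and 64.9% of probes were well above background on an array, and no spot was saturated. Arrays of the same group correlated across genes at Pearson r between 0.970 and 0.988, and arrays of different groups at r between 0.902 and 0.926, with genes not being independent replicates. Nothing says that the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

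The question was which transcripts differ when MEK5 is depleted, and the targeted gene came first. MAP2K5 fell in the shMEK5 cells, to a fitted 9.72% of its shControl level. Its normalized log2 signal was -1.96 ± 0.094 (SD, n = 3) in shControl and -5.32 ± 1.02 (SD, n = 3) in shMEK5, a log2 difference of -3.36 ± 0.46 (SE; limma adjusted p = 0.00254). Its probe, the only MAP2K5 probe on the array, has the coordinates 67985864 to 67995691 on chromosome 15, and it was well above background on 3 of 3 shControl arrays and 1 of 3 shMEK5 arrays. All 3 shMEK5 values lay below all 3 shControl values, which gave a two-sided exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. With slide as a block the log2 difference was -2.94 and missed the threshold (limma adjusted p = 0.0624), whereas within slide 1 alone the same difference had an adjusted p of 0.00262. Slide 1 holds a single shMEK5 array, so every test within it takes its spread from the shControl arrays and assumes that the lone array varies like them. Under the planned normexp correction, which raised dim spots to unequal floors, it was 0.12 (limma adjusted p = 0.867), and under the added correction from negative control spots -1.30 (limma adjusted p = 0.00433).

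MAPK7 did not pass the test, with a log2 difference of -0.20 ± 0.19 (SE; limma adjusted p = 0.477) and -0.39 within slide 1. Of the 12 measured members of the MEK5-ERK5 cascade, MAP2K5 included, 4 fell and 0 rose over all genes tested, and 4 fell and 1 rose when adjusted over the list alone. MEF2A, a transcription factor of the MEF2 family that ERK5 phosphorylates in part, fell by 1.88 on the log2 scale (adjusted p = 0.00465) and differed by -1.22 within slide 1. MEF2C fell by 0.86 (adjusted p = 0.0395) and MEF2B fell by 0.83 (adjusted p = 0.0214), with differences of -0.88 and -1.04 within slide 1. With slide as a block MEF2A and MEF2B passed and MEF2C did not (limma adjusted p = 0.2). The remaining members did not pass, with log2 differences of 0.38 for MEF2D, 0.21 for MAP3K2, -0.51 for MAP3K3, -0.52 for SGK1, -0.46 for SQSTM1, 0.05 for PRKCZ and 0.66 for PRKCI. The sign for MEF2D turned under quantile normalization, where it was -0.80 and past the threshold. Its probe was chosen again there and may be another one. As a list the cascade had a median of -0.49, and -0.65 within slide 1, and did not pass the test against other genes (camera adjusted p = 0.208), although it did with quantile normalization (camera adjusted p = 0.0188), within slide 1 alone with its single shMEK5 array (0.0284) and with the planned and the added normexp correction (0.00863 and 0.0193), but not with slide as a block (0.0671). With an estimated correlation it had an adjusted p = 0.604.

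**Figure D1:**
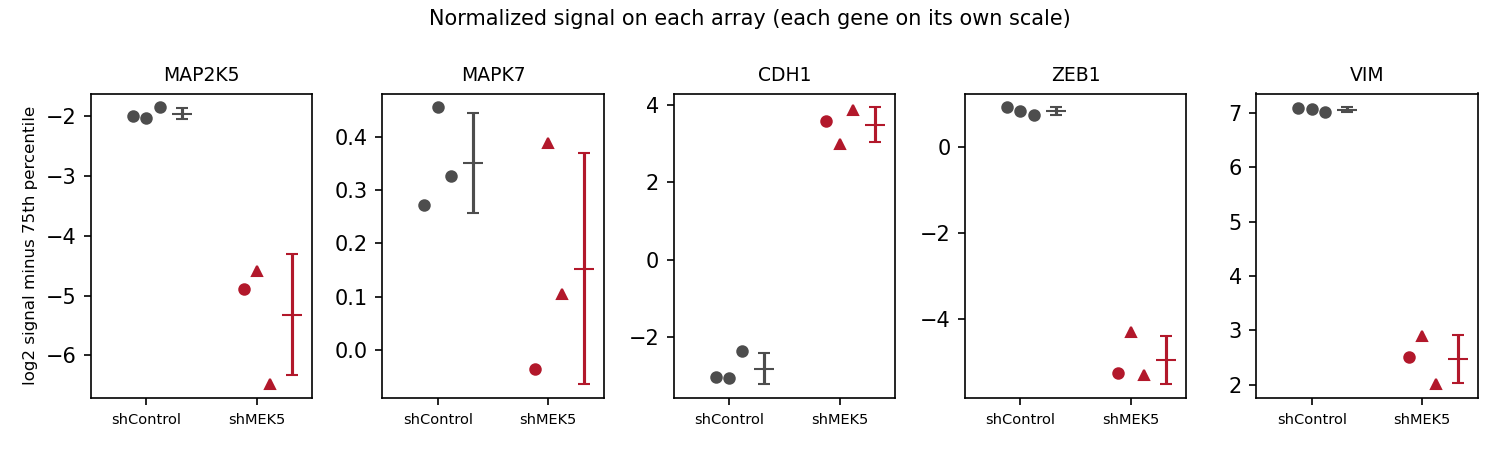
Normalized log2 signal of 5 genes on each array, with the mean and SD of each group (n = 3) beside the points and a separate vertical scale per gene. Circles are arrays of slide 1 and triangles those of slide 2, and for MAP2K5 the group means were -1.96 and -5.32.

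The shMEK5 cells differed from the shControl cells at 3284 of 14637 genes, of which 1659 were higher and 1625 lower. At least a 2-fold difference was seen at 2245 of them, and at least a 16-fold difference at 230. SV2B, a synaptic vesicle glycoprotein, rose at least 2434-fold, and NPY, which encodes neuropeptide Y, fell at least 663-fold. Other rises included ATP2C2, a calcium pump of the secretory pathway (at least 166-fold), BSPRY (at least 189-fold), MIR205HG, a microRNA host transcript (453-fold), FUT3, a fucosyltransferase (at least 107-fold), and S100A14, a calcium-binding protein (261-fold). SYK and VAV1, signalling proteins best known from leukocytes, rose at least 60.4-fold and at least 81.2-fold, ACOT11 rose 169-fold and LRG1 at least 61.1-fold. Falls included TENM2, a teneurin (at least 277-fold), PDPN, the membrane protein podoplanin (at least 138-fold), TMEM98 (at least 120-fold), LRRC38 (at least 117-fold), and FLI1, an ETS transcription factor (at least 104-fold). SELENBP1 fell at least 72.4-fold, KCNJ8 at least 57.6-fold, SSTR1 at least 36.5-fold, ITM2A at least 35.2-fold, and EPB41L3, a protein of the membrane skeleton, 197-fold. CACNG7 was lower by a probe above background on 3 of 3 shControl and 0 of 3 shMEK5 arrays, and no fold is given because another of its probes was above background in shMEK5. These genes and the epithelial genes OVOL1 and RAB25 made up the 12 rises and 12 falls named for their fitted size, which gives genes known only by a bound no true order, and all 24, with limma adjusted p between 1.02e-05 and 0.0001, also passed with slide as a block.

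Of all tested genes, 6666 (45.5%) had groups that did not overlap, where chance gives 10%. With slide as a block 1264 genes passed, 523 higher and 741 lower, and 1197 of these were among the 3284. Within slide 1, with its single shMEK5 array, 3283 of the 3284 had the same sign, in a comparison that shares 4 of the 6 arrays. At 3282 of the 3284 the groups did not overlap, which already fixes that sign. The shared sign therefore says nothing about slide. The planned normexp correction left 82 genes, and with each array scaled to its median the split was 2943 higher and 990 lower, because the median difference of all genes moved from 0.07 to 0.35. Without a filter on dim probes 1589 genes passed, and on the authors' deposited values 647 of 8971. The count was 1669, 1689 and 1777 without shControl replicate 1, 2 or 3, and 4942 without shMEK5 replicate 1. Without that shMEK5 array each group lay on a slide of its own, so no result of this omission separates group from slide. The planned normexp correction turned the sign of 13 other named genes past the threshold besides MAP2K5, and the authors' values that of SPRY4, VLDLR, BAD and POU5F1. In both settings the probe of a gene was chosen again, so a turned sign can come from another probe. Besides MAP2K5, 60 named genes no longer passed with slide as a block and kept their sign.

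**Figure D2:**
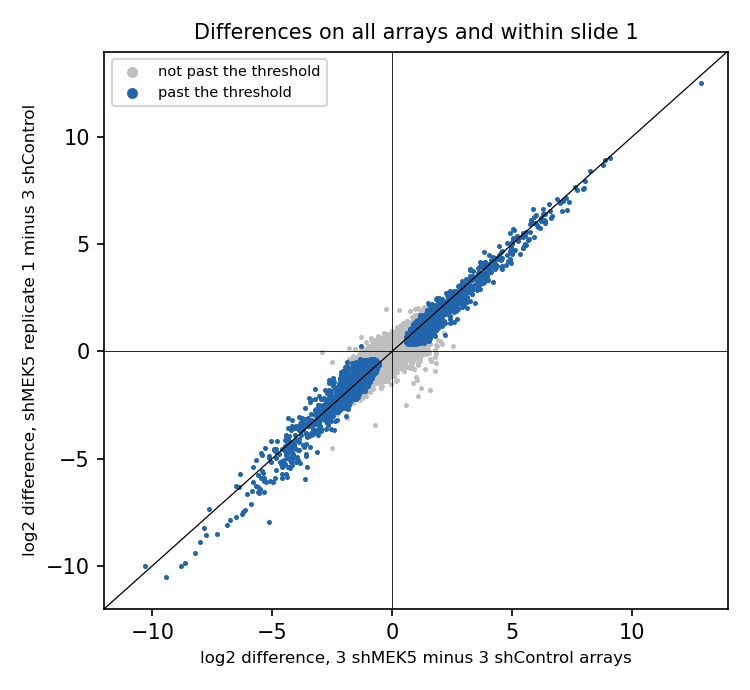
Log2 difference of each gene on all 6 arrays (horizontal) against that between shMEK5 replicate 1 and the 3 shControl arrays, all on slide 1 (vertical), with the line of equality. Blue points are genes past the threshold, 3283 of 3284 of which had the same sign on both axes, and the axes share 4 arrays. At 3282 of them the groups did not overlap, which already fixes the sign.

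Epithelial genes were higher in the shMEK5 cells and mesenchymal genes mostly lower. Of 24 measured epithelial genes, 22 rose and 0 fell, both over all genes and adjusted over the list alone. CDH1, which encodes E-cadherin, rose 78.7-fold (log2 6.30 ± 0.30, SE; limma adjusted p = 3.07e-05). OVOL1, a transcription factor, rose at least 72.2-fold and RAB25, a small GTPase, at least 94.2-fold. The list's median log2 difference was 2.91, and 2.71 within slide 1 (camera adjusted p = 3.38e-15; adjusted p = 0.177 with an estimated correlation). With slide as a block 17 of the 24 passed, all higher. Of 21 measured mesenchymal genes, 11 fell and 1 rose over all genes, and 12 fell and 3 rose adjusted over the list alone. ZEB1, a repressor of CDH1, fell 55.3-fold (log2 -5.79 ± 0.29, SE; limma adjusted p = 3.09e-05). VIM, the intermediate filament vimentin, fell 24.1-fold, ZEB2 20.8-fold with 1 of 3 shMEK5 arrays above background, and the N-cadherin gene CDH2 2.70-fold. TNC, a matrix protein, was the member that rose (1.64-fold, limma adjusted p = 0.0475; 0.279 with slide as a block, where 9 members fell and 0 rose). The median of this list was -1.02, and -0.83 within slide 1 (camera adjusted p = 0.00164; adjusted p = 0.396 with an estimated correlation).

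**Figure D3:**
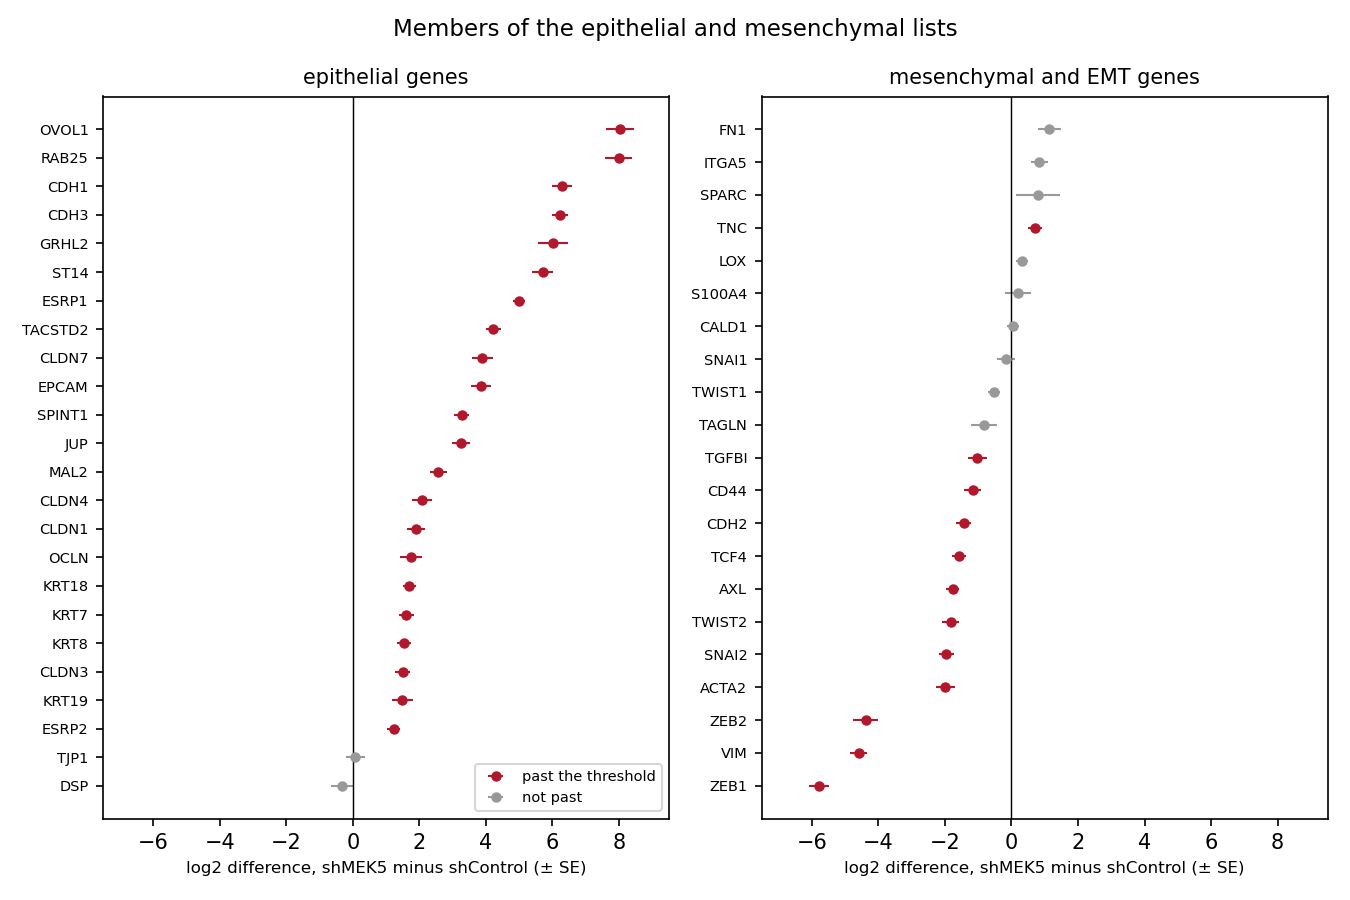
Log2 difference, shMEK5 minus shControl, with its SE for each measured member of the epithelial list (left, 24 genes) and the mesenchymal list (right, 21 genes). The points of OVOL1 and RAB25 are fitted values of genes not above background in shControl; red points passed the threshold, 22 rises on the left and 11 falls with 1 rise on the right.

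Genes of adhesion, invasion and growth factor signalling moved in both directions. Among 22 invasion proteases and inhibitors 5 rose and 6 fell, and 6 rose and 6 fell adjusted over the list alone (median 0.08, -0.22 within slide 1, 4 rises and 3 falls with slide as a block). MMP9, a gelatinase, rose 7.05-fold, MMP13 4.21-fold and MMP15 3.94-fold. SERPINB2, an inhibitor of plasminogen activators, fell 13.6-fold and TIMP1, an inhibitor of metalloproteinases, 4.61-fold. Of 23 integrins and basement membrane genes 2 rose and 5 fell, and 4 rose and 5 fell adjusted over the list alone (median 0.25, 0.04 within slide 1, 0 rises and 2 falls with slide as a block). ITGB4 rose 2.56-fold and LAMA3 1.60-fold, and NID1 fell 40.1-fold, ITGA1 28.3-fold and COL4A5 1.86-fold. Receptor tyrosine kinases and ligands numbered 24, with 6 rises and 5 falls, and 7 and 5 adjusted over the list alone (median 0.39, 0.15 within slide 1, 2 rises and 3 falls with slide as a block). FGFR2 rose 14.9-fold, IGF2 9.78-fold and ERBB3 5.33-fold, whereas FGFR1 fell 12.9-fold, AXL 3.40-fold and HBEGF 1.86-fold. Among 23 YAP/TEAD and TGF-beta responsive genes 3 rose and 8 fell, and 4 and 9 adjusted over the list alone (median -0.14, -0.31 within slide 1, 2 rises and 5 falls with slide as a block). BMP4 rose 4.28-fold and F3 2.74-fold, and ID3, an inhibitor of differentiation, fell 8.38-fold and ANKRD1 5.93-fold. None of these lists passed the camera test, with adjusted p between 0.281 and 0.777.

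Genes linked to MAP kinase signalling showed few joint shifts. Of 13 genes described as responsive to ERK5, 3 rose and 1 fell, the same counts as adjusted over the list alone (median 0.16, -0.13 within slide 1, 2 rises and 1 fall with slide as a block; camera adjusted p = 0.558). MMP9, THBD (4.19-fold) and MYC (2.40-fold) rose, and KLF2, a transcription factor induced by ERK5 in endothelium, fell 2.53-fold. Of 16 other MAP kinases and MAP kinase kinases 3 rose and 0 fell, again the same adjusted over the list alone (median 0.04, 0.01 within slide 1, 1 rise and 0 falls with slide as a block; camera adjusted p = 0.919). These were the p38 kinases MAPK13 (3.20-fold), MAPK12 (2.11-fold) and MAPK14 (2.05-fold). In the ERK1/2 feedback and output list 3 of 21 rose and 4 fell, the same adjusted over the list alone (median -0.13, -0.31 within slide 1, 0 rises and 3 falls with slide as a block; camera adjusted p = 0.491). AREG rose 3.86-fold, PHLDA1 2.64-fold and IER3 1.87-fold, and the feedback inhibitors SPRY4 and SPRY2 fell 3.04-fold and 2.48-fold and EMP1 2.17-fold. Of 16 AP-1 and immediate early genes 5 rose and 2 fell, and 5 and 4 adjusted over the list alone (median -0.03, 0.16 within slide 1, 1 rise and 0 falls with slide as a block; camera adjusted p = 0.891), with ZFP36 up 3.01-fold, FOSB up 2.59-fold, FOSL2 down 2.26-fold and EGR2 down 1.76-fold.

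Among genes of inflammation more members fell than rose, and most did not pass. Of 28 NF-kB targets, cytokines and chemokines 10 fell and 3 rose, and 11 fell and 3 rose adjusted over the list alone. IL1B fell 13.2-fold, IL11 7.10-fold and TNFAIP6 at least 6.86-fold, and TNFAIP2 rose 4.62-fold, CSF2 3.37-fold and NFKBIA, the inhibitor of NF-kB, 2.50-fold. The median was -0.52, and -0.44 within slide 1 (camera adjusted p = 0.00785; adjusted p = 0.396 with an estimated correlation). The counts were 5 and 1 with slide as a block. Without shMEK5 replicate 1, with each group then on a slide of its own, the list missed the threshold (camera adjusted p = 0.0503). Among 41 interferon-stimulated genes 10 fell and 4 rose, and 13 and 5 adjusted over the list alone (median -0.09, -0.40 within slide 1, 1 rise and 4 falls with slide as a block; camera adjusted p = 0.268, 0.0669 with slide as a block, and 0.0284 within slide 1 with its single shMEK5 array). IFIT1 fell 4.23-fold, IFI6 3.41-fold and IFI44 2.96-fold, and HERC6 rose 2.64-fold, CMPK2 2.62-fold and IFITM1 2.16-fold. Of 17 genes of MHC class I and antigen processing 2 fell and 1 rose, and 4 and 1 adjusted over the list alone (median -0.09, -0.16 within slide 1, 0 rises and 0 falls with slide as a block; camera adjusted p = 0.613), namely PSMB9 (2.21-fold down), ERAP2 (1.79-fold down) and NLRC5 (1.98-fold up).

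Genes of the cell cycle and of DNA repair seldom passed the test. For nonhomologous end joining 0 of 13 rose and 0 fell, also adjusted over the list alone (median 0.27, 0.19 within slide 1, 0 rises and 0 falls with slide as a block; camera adjusted p = 0.919), and the largest log2 difference was -0.68 for TP53BP1 (limma adjusted p = 0.0831). For homologous recombination and Fanconi anaemia 1 of 27 rose, FANCF (1.65-fold), and 0 adjusted over the list alone (median 0.26, 0.14 within slide 1, 0 rises and 0 falls with slide as a block; camera adjusted p = 0.286). In DNA damage signalling 1 of 23 fell over all genes and adjusted over the list alone, the kinase gene ATM (2.21-fold; median -0.23, -0.07 within slide 1, 0 rises and 0 falls with slide as a block; camera adjusted p = 0.229). Of 34 S phase genes 5 rose and 2 fell, and 6 and 2 adjusted over the list alone (median 0.15, 0.12 within slide 1, 2 rises and 0 falls with slide as a block; camera adjusted p = 0.455), among them CCNE2 (2.42-fold up), CDT1 (2.41-fold up), RFC3 (2.37-fold up), TYMS (2.04-fold down) and GINS4 (1.91-fold down). Of 33 mitotic genes 3 fell, KIF20A (2.06-fold), ASPM (1.82-fold) and NUF2 (1.67-fold), and 0 adjusted over the list alone (median -0.28, -0.19 within slide 1, 0 rises and 0 falls with slide as a block; camera adjusted p = 0.0799). That list had an adjusted p = 0.809 with an estimated correlation. It passed the preset camera test in 7 alternatives, with adjusted p of 0.00822 with quantile normalization, 3.62e-10 and 0.00231 with the planned and the added normexp correction, 0.0192 on the authors' values, 0.0198 without shControl replicate 3, 0.0203 without shMEK5 replicate 1 and 0.0387 with the replicate number as a block. Of 16 CDK inhibitors, D cyclins and RB family genes CCND3 rose 1.59-fold and CDKN2C fell 1.95-fold, and adjusted over the list alone 0 rose and 1 fell (median 0.11, 0.00 within slide 1, 0 rises and 0 falls with slide as a block; camera adjusted p = 0.985). Of 14 replication-dependent histones 3 fell and 0 rose, and 8 and 0 adjusted over the list alone, and with slide as a block 1 fell. The 3 were H1-2 (2.51-fold), H2BC21 (2.10-fold) and H2BC4 (1.92-fold), and probes of so similar a family can share signal. Their median was -0.84, and -0.47 within slide 1 (camera adjusted p = 0.00296; adjusted p = 0.604 with an estimated correlation; adjusted p = 0.0669 with slide as a block).

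Regulators of apoptosis included 9 rises and 3 falls among 32 genes, and 9 and 5 adjusted over the list alone (median 0.14, 0.18 within slide 1, 3 rises and 2 falls with slide as a block; camera adjusted p = 0.613). The BH3-only genes HRK, BIK and BMF rose 13.3-fold, 10.3-fold and 3.69-fold. CASP1, the inflammatory caspase, fell at least 22.1-fold, BIRC2 5.72-fold and BAD 1.58-fold. Of 23 p53-responsive genes 3 rose and 0 fell, and 2 and 0 adjusted over the list alone (median 0.13, -0.03 within slide 1, 2 rises and 0 falls with slide as a block; camera adjusted p = 0.710), namely ZMAT3 (3.19-fold), BBC3 (2.57-fold) and SESN1 (2.41-fold).

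Of 32 genes of cholesterol and fatty acid synthesis 10 rose and 2 fell, and 16 and 3 adjusted over the list alone, whereas with slide as a block 0 rose and 1 fell. SREBF2, a master regulator of sterol synthesis, rose 2.73-fold and NSDHL 2.49-fold, and PMVK fell 1.94-fold and TM7SF2 1.83-fold. The median was 0.62, and 0.43 within slide 1 (camera adjusted p = 0.00785; adjusted p = 0.604 with an estimated correlation; adjusted p = 0.0556 with slide as a block). Of 33 hypoxia and glycolysis genes 3 rose and 4 fell, and 3 and 5 adjusted over the list alone (median 0.08, also 0.08 within slide 1, 1 rise and 4 falls with slide as a block; camera adjusted p = 0.742), with NDRG1 up 4.48-fold, EGLN3 up 2.07-fold, ANGPTL4 down 3.91-fold, ENO2 down 3.61-fold and HK1 down 2.82-fold. Of 29 genes of the unfolded protein response and ATF4 targets 2 rose and 3 fell, and 1 and 2 adjusted over the list alone (median -0.04, -0.19 within slide 1, 0 rises and 1 fall with slide as a block; camera adjusted p = 0.536), with STC2 up 2.18-fold, MTHFD2 up 1.51-fold, VLDLR down 5.46-fold, PSAT1 down 2.19-fold and DDIT3 down 1.69-fold. Among 25 NRF2 targets and antioxidant genes 2 rose and 1 fell, and 1 and 0 adjusted over the list alone (median -0.03, -0.07 within slide 1, 1 rise and 0 falls with slide as a block; camera adjusted p = 0.919). GPX2, a glutathione peroxidase, rose 45.1-fold with 1 of 3 shControl arrays above background, AKR1B10 rose 3.35-fold and UGDH fell 2.57-fold. Of 16 heat shock genes DNAJB1 rose 2.32-fold and HSPB1 fell 1.86-fold, and 0 passed adjusted over the list alone (median 0.40, 0.43 within slide 1, 0 rises and 0 falls with slide as a block; camera adjusted p = 0.268, 0.108 with slide as a block, and 0.0284 within slide 1 with its single shMEK5 array).

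Lineage genes changed in part. Of 15 prostate luminal and androgen-responsive genes 5 rose and 1 fell, and 6 and 1 adjusted over the list alone (median 0.48, 0.32 within slide 1, 3 rises and 1 fall with slide as a block; camera adjusted p = 0.268). TMPRSS2, a serine protease, rose 40.1-fold with 1 of 3 shControl arrays above background, ACP3 passed with its reported probe above background on 0 of 3 shControl arrays and 3 of 3 shMEK5 arrays, so that no fold is given, and FOLH1, which encodes PSMA, fell 18.1-fold. Of 11 neuroendocrine and stem-like genes 2 rose and 4 fell, also adjusted over the list alone (median 0.04, 0.13 within slide 1, 2 rises and 2 falls with slide as a block; camera adjusted p = 0.825). SOX2 rose at least 15.0-fold, ALDH1A1 at least 4.27-fold, and POU5F1, whose pseudogenes can share its signal, fell 2.61-fold and ALDH1A3 2.31-fold. Of 13 genes of the small RNA machinery DICER1 rose 3.16-fold and AGO4 fell 1.89-fold, and 2 rose and 2 fell adjusted over the list alone (median 0.16, -0.01 within slide 1, 1 rise and 0 falls with slide as a block; camera adjusted p = 0.491). Of 20 ribosomal protein and housekeeping genes PGK1 rose 1.83-fold, and 0 passed adjusted over the list alone (median 0.00, 0.10 within slide 1, 0 rises and 0 falls with slide as a block; camera adjusted p = 0.985).

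Markers of other cell types were measured as well. Of 4 measured fibroblast markers, too few for a list test, 3 fell over all genes and adjusted over the list alone, COL5A1 (25.3-fold), COL6A3 (15.9-fold) and ACTA2 (3.96-fold), and ACTA2 is also on the mesenchymal list (median -2.99, -2.81 within slide 1, 0 rises and 3 falls with slide as a block). Of 8 leukocyte markers HCLS1 rose 8.25-fold and CD68 fell 2.19-fold, also adjusted over the list alone (median 0.09, 0.03 within slide 1, 1 rise and 0 falls with slide as a block; camera adjusted p = 0.863). Of 5 endothelial markers 2 fell, PECAM1 (4.12-fold) and ROBO4 (4.07-fold), and 3 adjusted over the list alone (median -0.84, -0.93 within slide 1, 0 rises and 0 falls with slide as a block; camera adjusted p = 0.244). Of 6 embryonic kidney markers, genes of the HEK293 line used to package virus, 3 fell over all genes and adjusted over the list alone, UCHL1 (at least 6.97-fold), NEFL (3.85-fold) and CDH2, which is shared with the mesenchymal list (median -1.14, -0.76 within slide 1, 0 rises and 2 falls with slide as a block; camera adjusted p = 0.229). Across all 35 tested lists 5 passed the camera test at the preset correlation and 0 with an estimated correlation. The planned normexp correction ended the call of the cholesterol list (adjusted p = 0.19) and brought those of antigen processing (0.0409) and the unfolded protein response (0.00214) past the threshold, as well as, with the sign of the median turned, those of hypoxia (0.00751) and housekeeping genes (0.00357). The median, mean and camera direction did not share 1 sign in 8 lists, those of AP-1 genes, invasion proteases, integrins, CDK inhibitors, hypoxia, NRF2 targets, neuroendocrine genes and leukocyte markers. Some folds rest on a group that was above background on part of its arrays. On 1 of 3 shControl arrays this was so for MIR205HG, ACOT11, FOSB and FGFR2, and on 2 of 3 for MMP13, ZMAT3, HERC6, NLRC5, EGLN3, BMP4, HRK and H2BC21. On 1 of 3 shMEK5 arrays it was so for NID1, ITGA1, VLDLR, ACTA2 and H2BC21, and on 2 of 3 for SERPINB2, ANKRD1, AGO4, FGFR1, COL5A1 and PECAM1.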

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

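The tests of slide and of the other splits of the arrays were chosen only after the result was seen.

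Probes without a gene symbol entered none of the gene comparisons. Of 1439 such probes, 144 passed the threshold, 97 higher and 47 lower in shMEK5. The largest rise was at chromosome 5, positions 82215492 to 82215551, with a log2 difference of 6.28 (limma adjusted p = 0.00444; above background on 1 of 3 shControl arrays), and the lowest fitted value belonged to a probe at chromosome 14, positions 59294858 to 59294919, above background on 0 of 3 shMEK5 arrays and at least 6.49-fold lower there (limma adjusted p = 0.00104).

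Many genes differed, with epithelial and mesenchymal genes at opposite ends, and a slide effect, a foreign cell line or subclones of PC3 could each produce that. Slide as the whole cause is argued against, because genes called from shMEK5 replicates 2 and 3 against shControl replicates 1 and 2 kept a median 0.635 of their difference between the remaining arrays of slide 1 (quartiles 0.291 and 0.968), with the same sign at 91.0% of 2762 genes. Copy number differences as the whole cause met the bound set against them. The correlation between genes 10 to 20 places apart was 0.0307, under 0.05, although above the highest of 1000 shuffles (0.00655). That bound was tried only on simulated blocks of neighbours shifted by 2 on the log2 scale. It cannot speak for smaller shifts, so copy number differences stay open. Another line in 1 group could not be excluded, because CTNNA1, deleted in PC3, was above background on 1 array only and its largest log2 difference, -1.48, rests on that probe. Of the 10 splits of the arrays 1, the real one, gave 3284 genes and the highest other gave 0. These are too few splits for a share under 0.05. Every other split mixes the groups, which puts their difference into the spread, whatever its cause. The splits therefore cannot tell causes apart, and MEK5 depletion and the outgrowth of a subpopulation stay open as untested.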

How the results depend on the processing

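The normexp correction from negative controls was chosen only after the result was seen; the other alternatives were planned. With quantile normalization, probes averaged, outlier spots kept, an intensity trend or slide as a random block, the counts of genes stayed within 1.5 times. The planned normexp correction left 82 genes (38 higher, 44 lower, 82 at least 2-fold) and 10 lists, because it lifted the dimmest spots to between 55.1 and 999 on different arrays. It turned MAP2K5 to 0.12, MEF2C to 0.033, EGR2 to 0.0069, ATM to 0.059, TNFAIP6 to 0.62, TM7SF2 to 0.087, VLDLR to 0.51, POU5F1 to 0.43, AGO4 to 0.55, H2BC21 to 0.72, ACTA2 to 0.47, PECAM1 to 0.38, ROBO4 to 0.13 and UCHL1 to 0.37, and the medians of the hypoxia list to -0.16 and the housekeeping list to -0.42. The negative control version gave 2846 genes (2421 shared) and MAP2K5 -1.30, with MEF2D at -0.71. With quantile normalization MEF2D was -0.80. The probe of MEF2D was chosen again in both settings and may be another one, and the cause was not tested. Median scaling gave 2943 higher and 990 lower, and no filter on dim probes 1589 (714 higher, 875 lower), with 22173 genes tested. With slide as a fixed block 1264 passed (523 higher, 741 lower, 1232 at least 2-fold), 3 lists passed and MAP2K5 was -2.94; slide 1 alone gave 977 higher and 8 lists. The authors' values gave 647 (370 higher, 277 lower, 647 at least 2-fold) over 8971 genes, with SPRY4 at 0.63, VLDLR at 0.48, BAD at 0.57 and POU5F1 at 0.71. Probes were chosen again there among those the authors kept, so these values may come from other probes, and the cause was not tested. Camera with an estimated correlation passed 0 lists and fry 16. Leaving out each array gave 1669 to 4942 genes, 767 to 2810 higher, 902 to 2132 lower, 1649 to 3073 at least 2-fold, MAP2K5 from -3.73 to -2.78 and 5 to 6 lists. The count was 1669, 1689 and 1777 without shControl replicate 1, 2 or 3, and 4942 without shMEK5 replicate 1, where each group lay on a slide of its own. With the replicate number as a block 2982 passed (2707 shared), with 6 lists. The deviations of genes from their group mean correlated between same-numbered shControl and shMEK5 arrays at 0.03, 0.06 and 0.22. By these deviations not every array was closest to its own number. Of 3169 values of named genes 2491 kept direction and side of the threshold, 639 lost the call, 6 gained it, 19 reversed and 14 without a call changed sign. MAP2K5 could not be tested among probes above background on all arrays, and lists were not run on single probes. Low signal over background limits dim genes such as MAP2K5.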

Other observations

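All tests of this part, on symbol families and on neighbouring genes, were chosen only after the result was seen. Of 35 tested genes with a keratin symbol, 13 rose and 3 fell in shMEK5 (one-sided Fisher's exact test for rises, adjusted p = 0.0242 over 374 tests, of rises and of falls in each of 187 symbol families), but 4 of the 13 were on the epithelial list. Among the 31 keratins outside that list 9 rose and 3 fell, and the same exact test missed the threshold (p = 0.0059, adjusted p = 0.606). The 9 included KRT6B, a keratin of stratified epithelia (log2 6.30 ± 0.56, SE, and 6.63 within slide 1), KRT6C (3.25), KRT6A (3.22) and KRT15, a basal keratin (2.85). The KRT6 genes are nearly identical and pseudogenes carry the same prefix, so probes can share signal. KRT75, KRT34 and KRT83 fell, by log2 differences of -3.88, -2.27 and -1.10. Of 22 collagen genes 9 fell and 3 rose, and the test for falls missed the threshold (adjusted p = 0.0605).

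Neighbouring genes on the long arm of chromosome 18 were lower together. Of 549 windows of 50 neighbouring genes, 16 had a median beyond all 1000 shuffles (-0.51 to 0.59), among them 3 lower on chromosome 18, 4 lower on chromosome 3 and 4 higher on chromosome 6. Adjacent windows share genes, so the 16 are not separate, whereas the shuffled range came from windows that do not overlap. The 4 on chromosome 6 lay between 106633866 and 161581337, with medians of 0.615 to 0.743. The chromosome 18 region, from 33840112 to 77514106, had a median log2 difference of -0.79 over 100 genes, 41 of which fell and 3 rose. The median within slide 1 was 0.835 of that on all arrays. A slide effect alone would make it smaller, but the region was picked on all 6 arrays, 4 of which are those of slide 1. Slide as the whole cause is therefore not excluded. In the region 83% of genes lay below the median of all genes, but the region was picked for its low medians, so this share decides nothing. A change in copy number, joint regulation of neighbours and slide all stay open.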
